A study of Citrus sinensis with 4 samples.

How the data were processed

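Gene expression was measured by RNA sequencing in the fruit peel of 'Newhall' navel orange, a seedless cultivar of sweet orange (Citrus sinensis), at 120 and 150 days after flowering. Per the labels' protocols, total RNA was taken with Trizol, mRNA was selected on oligo(dT) beads, and the fragmented mRNA was copied with random hexamers. No strand-marking step is described there. The series describes the 4 libraries as pools, with 2 independent biological replicates per stage. The labels do not say whether replicates of the same number share trees, a harvest day or a sequencing run.

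The deposited table holds FPKM, fragment numbers scaled to transcript length and to the number of mapped fragments, which the authors computed for each locus and library. Per the submitters' processing notes, TopHat and Cufflinks were used. Their versions, the genome build and the annotation are not given in the sources used here. The table has 31126 loci with Cufflinks XLOC numbers. Of these, 22810 carry 1 identifier that begins with Cs, 5914 carry 1 identifier that begins with orange1.1t, 503 carry several identifiers and 1899 carry no reference gene name. The 29655 distinct reference identifiers were looked up among the gene, locus-tag, synonym and accession entries of 29331 genes in the RefSeq table of the sweet orange assembly DVS_A1.0, and 0 were found. With this reference no gene could therefore be given a name or a function. Members of the gene lists fixed beforehand for wax, cutin, cuticle export, pigments, cell wall, flavonoids, terpenes, stress, division and other cell types could not be identified with it. These lists were therefore not tested. For the same reason no coordinates are given.

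FPKM values are not counts, so no count model was used. The depth of the libraries is unknown and no counting interval is given. Low values were examined for steps worth 1 fragment. For each pair of libraries, ratios of loci above 0 and under 0.4 FPKM in both were compared with ratios of whole numbers up to 5, times a common factor between 0.7 and 1.4, within a tolerance of 0.1%. Whole fragments cannot be recovered from these ratios alone, because the lengths of the loci are not known.

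Loci with a mean of at least 1 FPKM over the 4 libraries were tested, which kept 18727. The values were transformed to log2(FPKM + 1), and the stages were compared with limma 3.58.1 in R 4.3.3, with moderated variances, a mean-variance trend, no block and Benjamini-Hochberg adjustment over the tested loci. The threshold was an adjusted p of 0.05, two-sided. Changes are 150 minus 120 days on the log2(FPKM + 1) scale, which understates the change of low loci. A value of 0 can be a failed estimate in such a table, so loci are described as listed at 0, and no fold is given against a stage at 0. Of loci past the threshold with no overlap between the stages and a mean of at least 5 FPKM in the higher stage, the 2 with the largest rise and the 2 with the largest fall were to be named if no gene names could be had. Identifier classes were compared with Fisher's exact test. Pandas 2.3.3 and NumPy 2.4.6 served for the remaining steps.

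The test was tried on simulated data drawn around the mean of each of the 18727 loci, with 200 loci changed in each of 10 rounds. In the simulated comparison of 150 with 120 days, 2.04% of loci with a log2 change of 1 were recovered, 73.5% of those with a change of 2 and 93.1% of those with a change of 3. On average 4.10% of the simulated calls were false. Changes were put only on loci above about 5 FPKM. Noise was drawn independently for each library, so the simulated libraries shared no deviations. The adjusted threshold also depends on how many loci change. These shares therefore hold for the simulated setting and are not rates for the data.

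The alternatives were other pseudocounts (0.1 and 5), other filters on low values (none, or a mean of at least 5 FPKM), scaling to a common median or common quantiles, other variance models, leaving out each library, and the replicate number as a block. These, the test, the filter and the naming rule were set before the data were examined. A block that pairs the libraries by their value steps, a run on loci with a reference gene name, a run on loci above 0 in every library, and a minimum of 5 FPKM for loci listed at 0 at the other stage were added after the data were seen, as was the repeat of the test of loci without a reference gene name under each setting.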

Results

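Peel transcripts of 'Newhall' navel orange were profiled at 2 stages of fruit development, with 2 libraries at 120 days and 2 at 150 days after flowering. The series title places the comparison in the formation of the fruit cuticle during development and ripening. The cuticle is the layer of cutin and waxes that covers the outer wall of the epidermis. FPKM were available for 31126 loci, of which 7036 were listed at 0 in all 4 libraries. The loci above 0 numbered 22376 and 22215 in the 120-day libraries (replicates 1 and 2) and 22291 and 22455 in the 150-day libraries. The median FPKM of the 18727 tested loci lay between 14.6 and 15.1 in every library.

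Most of the summed FPKM came from loci with no reference gene name. FPKM is scaled to length, so a share of this sum is not a share of the fragments. The sum rested on a few very high loci. The median tested locus without a name had a mean of 8.97 FPKM, against 16.2 FPKM for loci with 1 Cs identifier. Loci with no reference gene name made up 80.3% and 76.95% of the sum in the 120-day libraries and 75.2% and 79.0% in the 150-day libraries. The 10 highest loci alone held between 43.7% and 51.2% of the sum in each library. The highest single value reached 471041 FPKM, in 150-day replicate 2. The sums themselves were 3971546 and 3382406 FPKM at 120 days and 3258399 and 4278581 FPKM at 150 days, so the spread within each stage covered the difference between the stages.

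Between 120 and 150 days, 535 of the 18727 tested loci (2.86%) changed, with 359 higher and 176 lower at 150 days (limma, Benjamini-Hochberg adjusted p of 0.05). The change was at least 2-fold on the FPKM + 1 scale for 472 of them, 313 higher and 159 lower. Among the 513 called loci above 0 in every library, the 343 rises had a median log2 change of 1.36 (quartiles 1.11 and 1.76) and the 170 falls a median of -1.35 (quartiles -1.65 and -1.14). Only 7 of these rises and 1 of these falls reached 8-fold. Abundant transcripts were among those that changed: 119 of the 1690 tested loci with a mean of at least 100 FPKM in either stage were called, 72 of them higher and 47 lower at 150 days. The stages did not overlap at 44.9% of all tested loci, where chance gives 33.3% for 2 libraries against 2. An unadjusted p under 0.05 was found at 3137 loci.

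**Figure D1:**
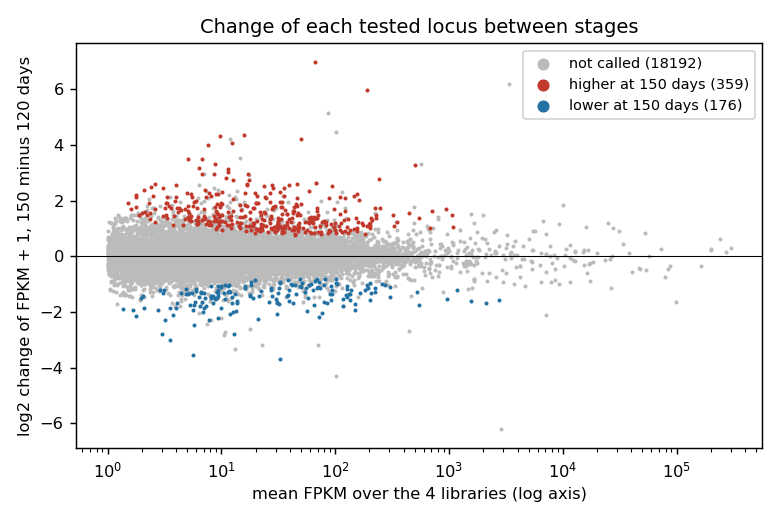
Log2 change of FPKM + 1 between the stages (150 minus 120 days) against the mean FPKM over the 4 libraries (log axis), 1 point per tested locus. The 359 loci higher at 150 days and the 176 lower ones are spread over loci from about 1 to over 1000 FPKM.

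The strongest rise among called loci above 0 in every library was that of the locus with the identifier orange1.1t03769 (XLOC_026636). It stood at 5.02 ± 1.14 FPKM at 120 days and at 375.5 ± 76.5 FPKM at 150 days (SD, n = 2). Its log2 change was 5.97 (SE 0.22, limma adjusted p = 0.00706), or 62.5-fold on the FPKM + 1 scale. XLOC_002695, a locus with no reference gene name, was listed at 0 in both 120-day libraries and stood at 179 and 88.0 FPKM in the 150-day libraries (limma adjusted p = 0.0101). Its zeros have no spread and can be failed estimates. It was the only locus at 0 throughout one stage and at 20 FPKM or more throughout the other. Dividing the libraries across the stages also gave such loci, 1 in each direction for one division and 0 and 1 for the other.

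The strongest fall among called loci above 0 in every library was that of XLOC_009094, another locus with no reference gene name. It went from 62.1 ± 6.61 FPKM at 120 days to 3.93 ± 0.050 FPKM at 150 days (SD, n = 2), a log2 change of -3.68 (SE 0.16, limma adjusted p = 0.00706). XLOC_030945, also without a reference gene name, stood at 7.30 and 15.1 FPKM in the 120-day libraries and was listed at 0 in both 150-day libraries (limma adjusted p = 0.0191). These zeros too have no spread and can be failed estimates. The call of XLOC_030945 was lost when either 150-day library was left out (limma adjusted p = 0.0762 without replicate 1 and 0.069 without replicate 2).

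**Figure D2:**
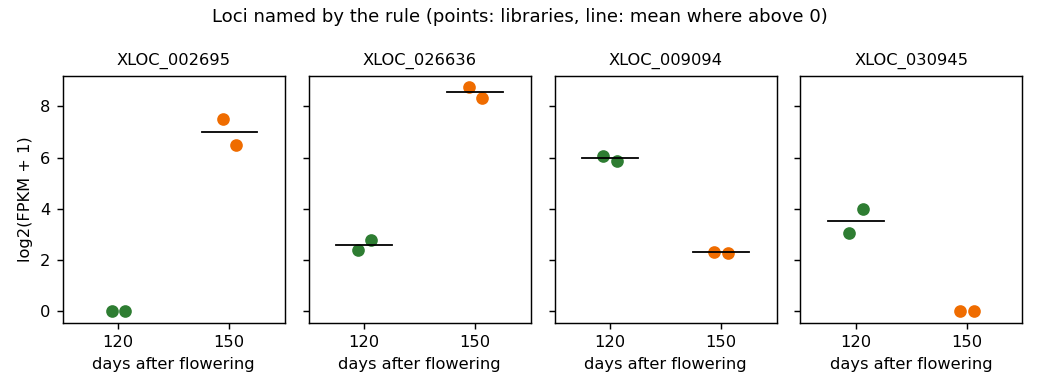
log2(FPKM + 1) of XLOC_002695, XLOC_026636, XLOC_009094 and XLOC_030945 in each library at 120 and 150 days after flowering. Points are libraries and lines are means of stages above 0. The libraries of the 2 stages do not overlap at any of the 4 loci.

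Loci with a single Cs identifier held most of the changes, with 268 higher and 133 lower at 150 days among 13808 tested. Of the 2531 tested loci with a single orange1.1t identifier, 35 were higher and 22 lower. Among the 1886 tested loci with no reference gene name, 48 were higher and 17 lower, and among the 502 with several identifiers 8 were higher and 4 lower. The share of called loci was 2.90%, 2.25%, 3.45% and 2.39% in these classes, and the test against the other classes passed the threshold for none of them (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p between 0.216 and 0.682 over the 4 classes). This depended on the fit. One fit had a term that pairs 120-day replicate 1 with 150-day replicate 2 and the remaining libraries with each other. It called 13.68% of loci without a reference gene name and 10.01% of the others (Fisher's exact p = 1.7e-06). Loci without a name were also called more often when any one library was left out. These fits have 1 residual degree of freedom each. In the fits with 2 residual degrees of freedom their share was higher as well. Fisher's exact p, not adjusted, was 0.0067 without the mean-variance trend, 0.0264 without a filter and 0.0314 with the filter at 5 FPKM. It lay between 0.0532 and 0.249 in the others, so whether such loci change more often is not settled. Loci listed at 0 in both libraries of one stage were few. There were 10 at 0 at 120 days and at 1 FPKM or more in both 150-day libraries, and 8 the other way round. Splitting the 4 libraries across the stages gave such loci in similar numbers, between 9 and 15 per direction.

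Part of the variation within the stages was shared by libraries of different stages. The first principal component of the log2 values held 53.1% of the variance and separated the stages. The second held 31.2% and set 120-day replicate 1 and 150-day replicate 2 apart from 120-day replicate 2 and 150-day replicate 1. One side of this division, 120-day replicate 1 with 150-day replicate 2, also stood out in the low FPKM values. The division is named by value step below, although a shared step was clear on that side only. Between 120-day replicate 1 and 150-day replicate 2, 82.8% of 1240 low loci differed by an exact ratio of whole numbers up to 5, times a common factor of 1.049. Between 120-day replicate 2 and 150-day replicate 1, 6.46% did, against a median of 0.76% over other common factors, and in the remaining 4 pairs of libraries between 2.36% and 2.65% did, against 1.17% to 1.25%.

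**Figure D3:**
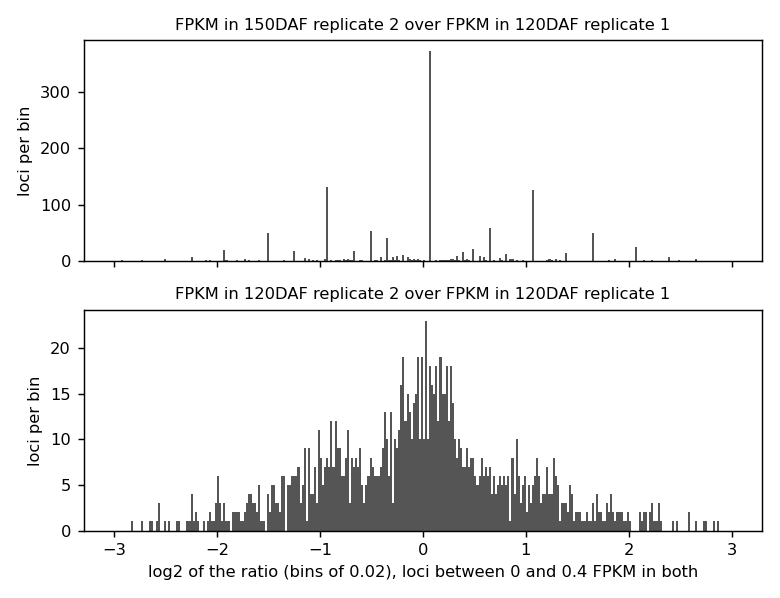
Ratios of FPKM between 2 libraries (log2 scale) for loci above 0 and under 0.4 FPKM in both, as numbers of loci per bin. Ratios between 150-day replicate 2 and 120-day replicate 1 pile up at a few values, while ratios between the 120-day replicates are spread out.

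The stage comparison was therefore repeated within these pairs, each of which holds 1 library per stage. In 120-day replicate 1 against 150-day replicate 2, 1193 loci differed at least 2-fold, and in 120-day replicate 2 against 150-day replicate 1, 1279 did. At 665 loci the difference was at least 2-fold in both pairs, with 407 higher in both, 198 lower in both and 60 in opposite directions. The pairs were formed after the values had been seen. Their changes, which share no library, had a correlation of r = 0.54 across loci, which are not independent replicates. When the libraries were paired by replicate number instead, which also leaves no library in common, r was 0.25. There 613 loci differed at least 2-fold in both pairs, 360 higher in both, 173 lower in both and 80 in opposite directions. The higher r of the first pairing follows from its choice. It joins libraries that deviated from their stage means in the same direction (r = 0.33), and pairing by number joins those that deviated in opposite directions (r = -0.33). With 2 libraries per stage the deviations mirror each other, so these are 1 result with opposite signs. For XLOC_026636 the log2 change was 5.95 and 5.98 in the 2 pairs, and for XLOC_009094 it was -3.79 and -3.56. With the pair as a term in the limma model, 1944 loci passed the threshold, 1157 higher and 787 lower, and these included all 535. The term follows the division of the second principal component and was chosen from the same values. It leaves the log2 changes as they were, with 1 residual degree of freedom. The higher count and the kept 535 are therefore no separate support for the calls.

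**Figure D4:**
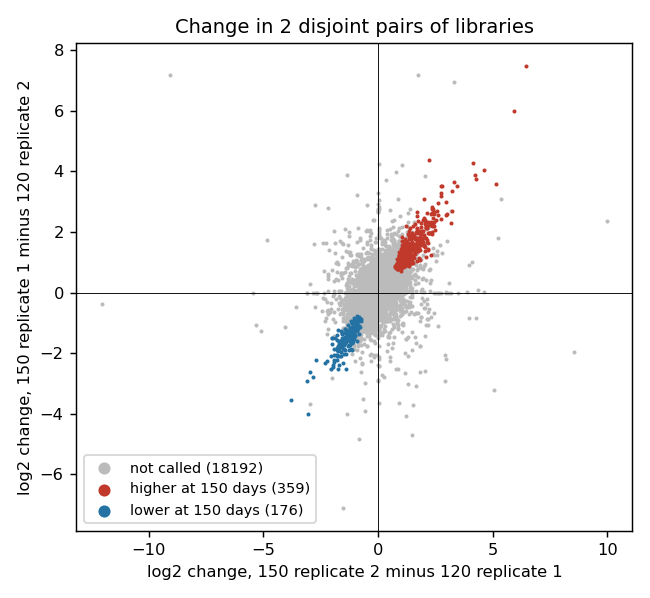
Log2 change of FPKM + 1 from 120-day replicate 1 to 150-day replicate 2 (x axis) and from 120-day replicate 2 to 150-day replicate 1 (y axis), 1 point per tested locus. At 407 loci the change was at least 2-fold higher in both pairs, at 198 at least 2-fold lower in both. Called loci share a sign in both pairs by construction, since their stages do not overlap.

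With 2 libraries per stage the number of calls rested on each of them. Without 120-day replicate 1 the call number was 313, without 120-day replicate 2 it was 146, without 150-day replicate 1 it was 39 and without 150-day replicate 2 it was 15, with 1 residual degree of freedom in each of these fits.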

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

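The number of calls depended on the filter, the libraries and the block. The sign of a called locus is no check, since the stages overlapped at 0 of the 535 loci. Under the other pseudocounts, the filter at 5 FPKM, both scalings and both variance models, between 422 and 578 loci were called, and 390 to 535 of these were among the 535. The count of at least 2-fold changes fell to 304 with a pseudocount of 5, which compresses folds by its construction. With no filter 24090 loci were tested and 162 were called, 116 higher and 46 lower, 162 of them at least 2-fold. Leaving out one library gave 15 to 313 calls (11 to 222 higher, 4 to 91 lower, 15 to 313 at least 2-fold), with the lone library of a stage assumed to vary like the other stage. With the replicate block there were 870 calls, 560 higher and 310 lower, 826 at least 2-fold, and 496 of the 535 were among them. This fit has 1 residual degree of freedom, and its loci with an unadjusted p under 0.05 fell from 3137 to 2479. Libraries with the same number deviated in opposite directions (r = -0.33), which is the r of the crossed pairing with its sign reversed. The labels do not say what libraries of the same number share. With the numbers crossed there were 1944 calls, 1157 higher and 787 lower, 761 at least 2-fold, also with 1 residual degree of freedom. On loci with a reference gene name there were 749 calls, of which 269 were lower, against 470 of the 535 that carry such a name. On loci above 0 in every library there were 644 calls, 429 higher and 215 lower, 542 at least 2-fold. Loci without a reference gene name were called more often than the others without trend, without a filter and with the filter at 5 FPKM (Fisher's exact p = 0.0067, 0.0264 and 0.0314), without any one library, and with the replicate block (11.03% against 3.93%, p = 4.81e-34) or the crossed pairing. The cause of these differences was otherwise not tested. Of 59 alternative values of the 4 named loci, 57 kept direction and threshold, and 2 kept direction only. These 4 loci were chosen for the largest changes without overlap, so their direction is no check and their threshold a weak one. The loci listed at 0 at 120 days fell from 10 to 5 when 5 FPKM were asked for at 150 days, and those listed at 0 at 150 days from 8 to 3. Without one library they were 43 to 50 and 26 to 32. Alternatives for counts and for gene lists were not run, since the table has neither counts nor gene names. The depth is unknown. Changes near 2-fold were mostly missed in the simulated data, whose setting differed from the data, so how many were missed here is unknown.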

Other observations

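The tests of the library split, of the share of rises, of the number of neighbouring calls and of the Cs5g series were chosen after their results were seen, while the test of the correlation between neighbouring loci was set before its value was known.

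Changed loci tended to lie next to each other in the numbering of the table. Among 12901 pairs of consecutive tested loci, 26 pairs were called in the same direction, where shuffled calls gave 5.81 on average and 11 at the upper bound of the central 95% of shuffles (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give). Pairs called in opposite directions numbered 6, against 4.65 after shuffling (permutation p = 0.32). One reference gene cut into several loci is argued against as the whole cause. Among loci with 1 different reference identifier each, 19 same-direction pairs remained, 15 of them higher and 4 lower at 150 days, against 4.43 after shuffling. Genes that the reference itself splits into several identifiers could not be recognized, so that case stays open. A technical tie between neighbouring values, such as reads shared by adjacent copies, stays open. The rank correlation between neighbours was 0.091 for the stage change and 0.010 and 0.0344 for the 2 contrasts within stages, with a shuffled SD of about 0.010. Shared reads would pass a change of 1 copy on to its neighbour. They too would give the highest correlation where the libraries differ most, at the stage change, so these values cannot decide. The value of 0.0344, for the replicate number, was above the highest of 1000 shuffles (0.0318), so a weaker tie between neighbours was present without a stage difference. Shared regulation of neighbouring genes, or runs of related genes, may account for the pattern, and neither was tested because the loci have no sequence or function here.

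The split of the libraries by 120-day replicate 1 and 150-day replicate 2 against the others has a candidate explanation in how the FPKM were computed. Exact whole-number ratios in 82.82% of low loci would follow if both libraries divided whole fragments by the same length for each locus, as under a common fragment-length model, while the other side of the division, 120-day replicate 2 with 150-day replicate 1, had 6.46% against a background of 0.76%, and the other 4 pairs at most 2.65%. The split by value step called 2 loci and the split by replicate number 0 (1809 and 183 at an unadjusted p under 0.05 in limma), against 535 for the labelled stages. These counts follow from the labelled stages being the largest difference, so they do not exclude a swap of stage labels, which stays open. Libraries prepared or sequenced together could give the same division, and the labels do not tell. There are only 3 ways to split the 4 libraries in pairs, and 1 of them, the labelled one, reached 535 calls, with 2 as the highest of the others. This is too few for a share under 0.05.

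More loci rose than fell, 67.1% of the calls. Scaling between the libraries is argued against as the source, because 63.96% of the calls rose after quantile normalization. The median log2 change of all tested loci was -0.01, near 0. Scaling to a common median therefore moved too little to test scaling as the source. The share was 59.5% with the crossed pairing as a block. No biological explanation was tested.

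At 2 loci with high values, the division by value step gave a listed 0 in both libraries of one side. Cs3g11200 (XLOC_006671) stood at 3863 FPKM in 120-day replicate 1 and 1871 FPKM in 150-day replicate 2 and was listed at 0 in the other libraries. XLOC_016872, which has no reference gene name, stood at 11632 FPKM in 120-day replicate 2 and 9345 FPKM in 150-day replicate 1 and was listed at 0 in the other libraries. At a minimum of 20 FPKM the division by value step had these 2 loci and the other 2 splits of the libraries had 1 each, which is no clear excess. At a minimum of 1000 FPKM, which was not set beforehand, the other 2 splits had 0 such loci. In all, 32 loci were at 0 in one library and at 20 FPKM or more in another, 25 of them without a reference gene name.

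The called loci whose identifiers begin with Cs5g were 31 higher and 32 lower at 150 days, while the other Cs series together had 237 higher and 101 lower (two-sided Fisher's exact p = 0.00201, adjusted p = 0.0181 over 9 series). The difference did not hold with the crossed pairing as a block (110 higher and 89 lower against 727 and 493, Fisher's exact p = 0.277) or on loci with a reference gene name (p = 0.161), and without 150-day replicate 2 there were 0 called Cs5g loci to compare. Neighbouring loci are not independent, so these p-values are too small.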
